A study of Trichophyton mentagrophytes with 9 samples.

How the data were processed

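Poly-A RNA of Trichophyton mentagrophytes mycelium was sequenced in 9 samples, 3 without Trichoderma and 3 each with 10 and 100 ug/ml. The deposited table lists 8380 genes, of which 7860 are named gene models and 520 are loci without a model name, on 522 contigs. It holds raw counts per gene and sample, as the authors deposited them, made with tools that include HISAT2 2.0.5 and featureCounts 1.5.0-p3, per the submitters' processing notes. The genome build, the annotation version and the strand setting are not given in the sources used here. The deposited FPKM values follow from the counts, the gene length and a total per sample that differs from the sum of the counts. The gene length in the deposited table, in bases, was a multiple of 3 for 99.52% of the gene models, as a coding length is. The authors' comparison columns hold a mean of scaled counts per group, which was not used here. They also hold a log2 fold change per gene by the authors, and a p-value with its adjusted form, deposited for each of 3 comparisons. DESeq2 1.20.0 is named among the tools, per the submitters' processing notes.

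All tests here used the raw counts. FPKM and the authors' fold changes and p-values served for checks and for the counts of genes in the authors' deposited table. Total counts were 18950514, 15904732 and 17445845 in the control samples, 17163859, 16927000 and 16887933 at 10 ug/ml, and 16633516, 18045074 and 19902831 at 100 ug/ml. In all, 243 genes had 0 counts in every library, and 1771 gene models had neither Swiss-Prot nor Pfam text. Genes were filtered by filterByExpr with its defaults (minimum count 10), which left 7920. Counts were scaled by TMM factors (0.869 to 1.17) and fitted with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood with robust estimation, in one fit of the 9 samples. The common dispersion was 0.0847, a biological coefficient of variation of 0.291. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 on the adjusted p. Levels are counts scaled by TMM to CPM. SE is an approximate standard error, the absolute log2 fold change divided by the square root of the F statistic of its test. It may be too small for genes with few counts. The sample numbers were not used as pairs.

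Lists were made by matching words in the Swiss-Prot and Pfam text. Of 32 lists fixed before the data were examined, 30 had genes, and 2 for RNA quality (mitochondrially encoded genes and ribosomal RNA) matched 0 genes. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, for lists with at least 5 genes, and p-values were adjusted over the lists. The same test with the correlation estimated per list, and fry, were run beside it. Lists may share genes, and members follow the words in a description, so a list can hold genes that do other work.

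Genes were named by a rule. For each dose against control these were the 10 largest rises and 10 largest falls among genes past the threshold, with a mean of at least 50 counts in the higher group, no overlap between replicates and a real description, and 5 and 5 for dose against dose. Also named were the 2 members with the smallest adjusted p in each direction for each list that passed, and the largest rise and fall in each comparison whatever the description. In each list described, up to 4 members with the smallest adjusted p could be named. Figures were drawn with matplotlib 3.10.9.

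The gene test was tested on simulated data with 200 changed genes. These had a mean of at least 50 counts, and each simulated gene had only the spread typical of its level. For 10 ug/ml against control the test ran on 7903 genes, recovered 99% of 4-fold and 38% of 2-fold changes and made 10 false calls. For 100 ug/ml against control it ran on 7899 genes, with 99%, 37% and 6. For 100 against 10 ug/ml it ran on 7902 genes, with 100%, 28% and 8. A list shifted on purpose at 100 ug/ml was called and 0 other lists were. Genes in that simulation were independent of each other, whereas in the real lists the estimated correlation reached 0.741. It therefore could not show how often the list test calls lists of correlated genes by chance. The test of adjacent genes, on 7920 genes, gave -0.02 for independent values and 0.51 for values built with a correlation of 0.5. The family test, on 2000 genes, called the 1 built-in family and 0 others.

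The alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (CPM of at least 5 and 10 counts in 3 or more libraries), a fit of the 2 groups compared, a replicate block, no robust estimation, leaving out each library in turn, and a fold threshold of 2. Scaling by library totals and matching by Swiss-Prot name alone were added after the data were seen, as were list counts without replicate 2 of 100 ug/ml. Reads were not analysed here.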

Results

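The poly-A RNA of Trichophyton mentagrophytes mycelium was sequenced in 9 libraries. This fungus is a dermatophyte, a mould that grows on the keratin of skin, hair and nails. Colonies had grown for 6 days on SDA plates that carried Trichoderma at 0, 10 or 100 ug/ml, with 3 libraries at each level, and the plates without Trichoderma were the control. The labels do not say which preparation of Trichoderma was added. The sample titles write uL beside the same numbers, and doses are given here in ug/ml, as in the treatment label. Total counts were 15904732 to 19902831 per library over 8380 genes, and 8063 to 8081 genes had a count above 0. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The gene lists, the tests of the 3 comparisons and of the lists, and the rule for naming genes were fixed before the data were examined.

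On the first principal component of log2 expression (54.7% of the variance) the control libraries lay at -53.2 to -18.1, the 10 ug/ml libraries at -22.1 to 3.04 and the 100 ug/ml libraries at 32.1 to 62.1. Control replicate 2 lay at -18.1, among the 10 ug/ml libraries. Its Spearman correlations were 0.976 to 0.982 with the 10 ug/ml libraries, and 0.973 and 0.961 with the other control libraries. Replicate 2 of 100 ug/ml lay at 41.3 on the second component (14.4%), against -27.2 to 14.0 for the other 8 libraries. Loci without a gene model name took 3.82% of its counts and 1.57 to 2.52% of the counts of the others. Spearman correlations across genes were 0.961 to 0.982 between control libraries, 0.972 to 0.988 between 10 ug/ml libraries and 0.926 to 0.963 between 100 ug/ml libraries. Between groups they were 0.939 to 0.982 for control and 10 ug/ml, 0.824 to 0.935 for control and 100 ug/ml, and 0.875 to 0.956 for the 2 doses.

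**Figure D1:**
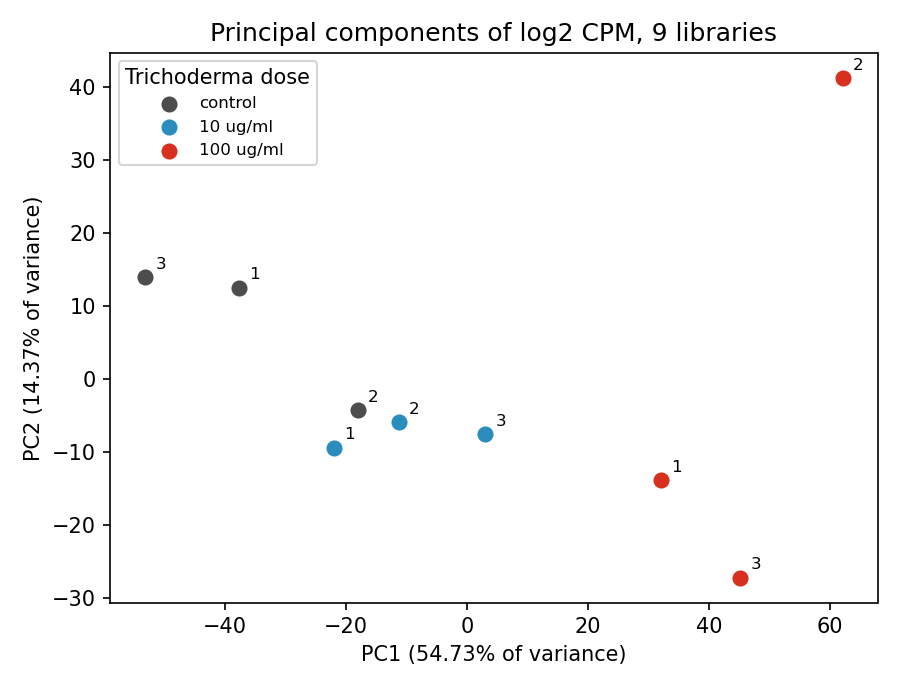
Principal components 1 (horizontal, 54.7% of the variance) and 2 (vertical, 14.4%) of log2 expression, one point per library, by group. The 100 ug/ml libraries lie at 32.1 to 62.1 on component 1, and their replicate 2 lies at 41.3 on component 2.

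The comparison of 100 ug/ml with control asked which transcripts differed in mycelium grown on the higher level of Trichoderma. Among the described genes named by the rule, the largest rises were in single transcripts of secreted proteases. Subtilisin-like protease 11 (TMEN_6501, contig BFBS01016318.1, 25864 to 27264) rose from 5.51 ± 1.29 to 661 ± 554 CPM (scaled counts; mean ± SD, n = 3), a log2 fold change of 6.90 ± 1.04 (SE; edgeR adjusted p = 0.00282). A neutral protease 2 homolog (TMEN_8004, BFBS01016464.1, 22416 to 23617) rose from 8.99 ± 7.87 to 464 ± 381 CPM, by 5.68 ± 0.79 on the log2 scale (adjusted p = 0.00206). Subtilisin-like protease 4 (TMEN_4279, BFBS01016026.1, 7637 to 9024) rose from 16.1 ± 3.31 to 585 ± 464 CPM, by 5.19 ± 0.62 (adjusted p = 0.00121). Subtilisins are serine proteases, and dermatophytes secrete several of them to break down protein such as keratin. Subtilisin-like proteases 5 (TMEN_6926) and 1 (TMEN_4057) rose by 3.90 ± 0.57 and 3.63 ± 0.50 on the log2 scale (adjusted p = 0.00206 and 0.00188). The sizes moved with single libraries. Without replicate 2 of 100 ug/ml the log2 fold change was 6.17 for TMEN_6501 (6.19 with limma-voom) and 4.37 for TMEN_4279. Without replicate 3 of 100 ug/ml it was 4.74 for TMEN_8004 and 3.31 for TMEN_6926, and without control replicate 1 it was 6.70 for TMEN_8004.

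Other single genes rose as well. A high-affinity glucose transporter (TMEN_7206) rose by 4.14 ± 0.78 (adjusted p = 0.00526), and a sulfotransferase family gene (TMEN_2094) by 3.98 ± 0.39, from 6.77 ± 1.25 to 107 ± 53.0 CPM (adjusted p = 0.000428). Geranylgeranyl diphosphate synthase (TMEN_7583), which makes the precursor of diterpenes and of prenyl groups on proteins, rose by 3.98 ± 0.64 (adjusted p = 0.0031). A gene with a phosphopantetheine attachment site (TMEN_2619, BFBS01015821.1, 10545 to 15734), the carrier domain of peptide and polyketide synthases, rose from 57.4 ± 16.0 to 806 ± 713 CPM (3.81 ± 0.58; adjusted p = 0.00245). A C2H2 zinc-finger gene (TMEN_5620) rose by 3.61 ± 0.63 (adjusted p = 0.00425). Without replicate 2 of 100 ug/ml TMEN_7206 gave 2.77, TMEN_7583 3.31 and TMEN_2619 2.79. Without control replicate 2 TMEN_7583 gave 4.58, and without replicate 1 of 100 ug/ml TMEN_5620 gave 2.53.

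Among the falls, a terpene synthase family gene (TMEN_5830, BFBS01016237.1, 352163 to 353899) went from 107 ± 35.7 to 4.03 ± 1.11 CPM (-4.73 ± 0.41; adjusted p = 0.000428), and its neighbour TMEN_5829, a Pal1 cell morphology gene, fell by 3.44 on the log2 scale (SE 0.45; adjusted p = 0.00132). A Zn(2)-Cys(6) transcription factor gene (TMEN_5603, BFBS01016230.1, 43 to 3603) fell from 1427 ± 312 to 95.8 ± 16.0 CPM (-3.90 ± 0.39; adjusted p = 0.000428). An insulin-induced protein family gene (TMEN_6115, BFBS01016249.1, 51322 to 52552), of a family known to control sterol synthesis, fell from 2001 ± 871 to 148 ± 45.4 CPM (-3.75 ± 0.47; adjusted p = 0.00109). A LysM domain gene (TMEN_8673, BFBS01016482.1, 205780 to 207193), with a domain that binds chitin, fell from 248 ± 93.3 to 22.3 ± 6.16 CPM (-3.47 ± 0.34; adjusted p = 0.000428). A zinc-type alcohol dehydrogenase-like gene (TMEN_8383) fell from 2198 ± 622 to 118 ± 65.3 CPM (-4.22 ± 0.79; adjusted p = 0.00494). An endo-chitosanase gene (TMEN_6998) gave -3.64 ± 0.66 (adjusted p = 0.00454). Glutamate decarboxylase (TMEN_1041, BFBS01007551.1, 11172 to 12728) gave -5.16 ± 0.89 (adjusted p = 0.00451), with control libraries at 103 ± 115 CPM and 2.89 ± 1.18 CPM at 100 ug/ml. A pair of genes of ergot alkaloid synthesis, easF (TMEN_6521) and chanoclavine-I dehydrogenase (TMEN_6522), gave -5.57 ± 0.77 and -4.67 ± 0.52 (adjusted p = 0.00148 and 0.000684), from 252 and 237 counts in the control libraries to 6 and 11. The largest fall of any gene was in TMEN_4201, which has no description, from 795 ± 324 to 7.92 ± 5.8 CPM (-6.65 ± 0.73; adjusted p = 0.000865). Without control replicate 1 TMEN_1041 gave -3.68, and without control replicate 3 TMEN_6998 gave -2.94. Without replicate 1 of 100 ug/ml TMEN_6521 gave -7.43 and TMEN_4201 -7.34.

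**Figure D2:**
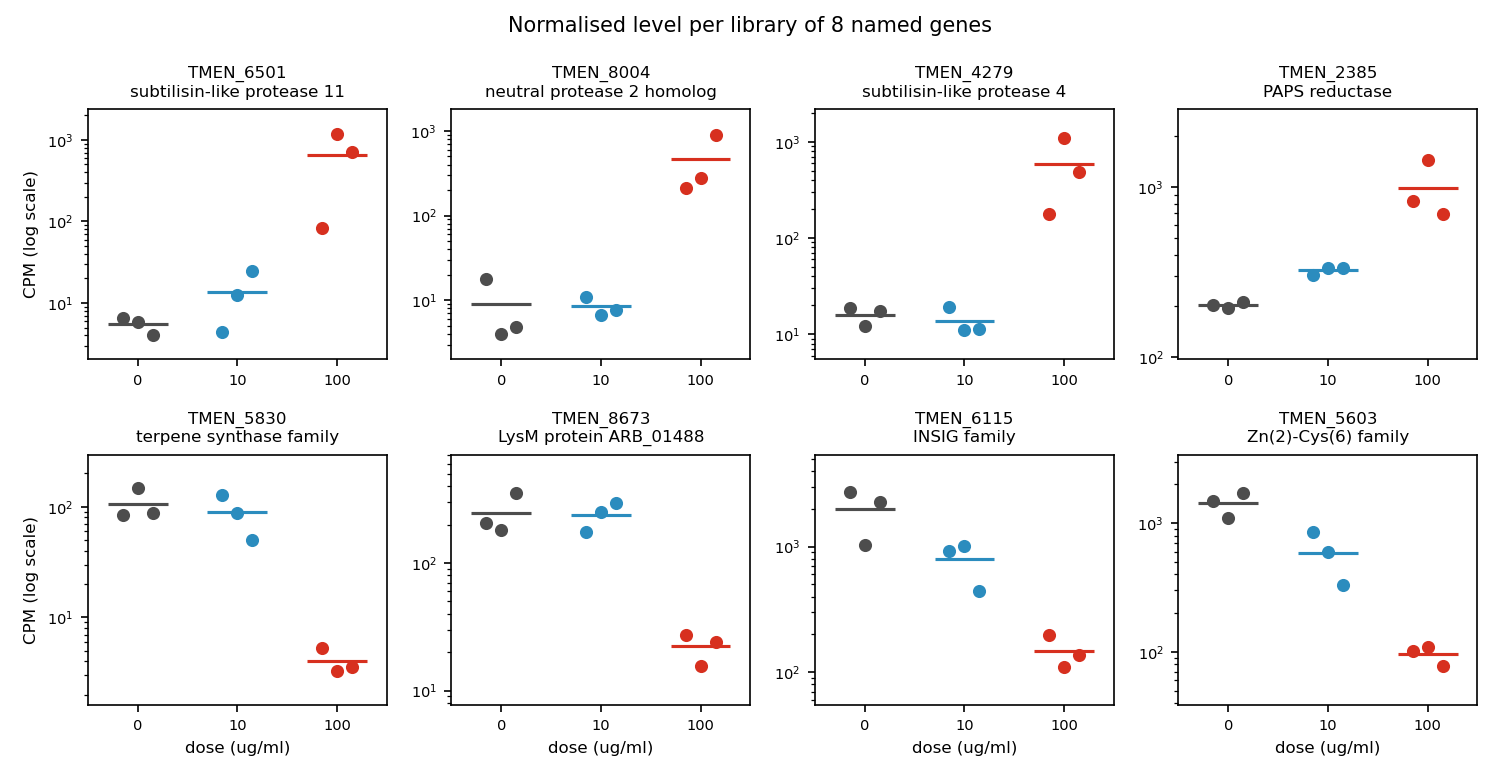
Expression (CPM, log axis) of 8 named genes in each library, by Trichoderma level; points are libraries. Subtilisin-like proteases 11 and 4 and the neutral protease lie higher at 100 ug/ml, while TMEN_5830, TMEN_8673, TMEN_6115 and TMEN_5603 lie lower.

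Of 7920 genes tested with edgeR's quasi-likelihood test, 2491 (31.5%) changed at 100 ug/ml, 1272 of them higher and 1219 lower, and 868 and 745 by 2-fold or more. Without replicate 2 of 100 ug/ml, 2074 genes passed. The count was 1320 without control replicate 1 and 1170 without control replicate 3. Higher and lower calls were 1513 and 1017 under upper-quartile factors and 1757 and 765 under library totals, which moved the median log2 fold change of all genes from 0.04 to 0.14 and 0.27. The groups did not overlap for 3502 genes (44.2%, where chance gives 10%). In the authors' deposited table the count was 2326 genes, 1203 higher and 1123 lower, and 2210 of them passed here with the same sign.

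Peptidases of secreted families stood higher as a list. Of 88 genes tested, 33 rose, 9 fell and 46 did not pass, 36 and 12 when adjusted over the list alone, and 31 rose and 8 fell without replicate 2 of 100 ug/ml, or 40 and 8 under library totals. The median log2 fold change was 0.65 (camera adjusted p = 0.00444; adjusted p = 0.279 with an estimated correlation). Beside the subtilisins, a serine protease K12H4.7 (TMEN_8842) rose by 2.92 ± 0.34 (adjusted p = 0.000865), and an aspartic-type endopeptidase CTSD (TMEN_5093) fell from 178 ± 19.6 to 24.4 ± 3.42 CPM (-2.86 ± 0.35; adjusted p = 0.001). A zinc metalloproteinase (TMEN_2766) gave -1.11 ± 0.22 (adjusted p = 0.00541).

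Antioxidant and glutathione enzymes stood higher as a list, with 38 of 84 genes higher, 4 lower and 42 not past the test. The counts were 44 and 4 adjusted over the list alone, and 34 and 2 without replicate 2 of 100 ug/ml, or 48 and 2 under library totals. The median was 0.76 (camera adjusted p = 1.55e-06; adjusted p = 0.358 with an estimated correlation). A phosphoadenosine phosphosulfate reductase (TMEN_2385), which draws electrons from thioredoxin in sulfate assimilation, rose from 202 ± 7.90 to 986 ± 394 CPM (2.29 ± 0.29; adjusted p = 0.00121). Glutathione S-transferases couple glutathione to reactive compounds. Of their genes, TMEN_9343 rose by 2.23 ± 0.32 and TMEN_8331 by 2.95 ± 0.43 (adjusted p = 0.00165 and 0.00202). The catalase easC gene (TMEN_6523), part of ergot alkaloid synthesis, gave -2.45 ± 0.52 (adjusted p = 0.00686). A heme-binding peroxidase (TMEN_5134) gave -1.62 ± 0.45 (adjusted p = 0.0198), with adjusted p = 0.068 and 0.0813 without control replicate 1 or 3, and 0.0535 and 0.0591 without replicate 2 or 3 of 100 ug/ml.

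Ergosterol and isoprenoid synthesis, which makes the main sterol of fungal membranes, had 17 of 48 genes higher, 3 lower and 28 not past the test. The counts were 18 and 4 adjusted over the list alone, and 14 and 3 without replicate 2 of 100 ug/ml, or 21 and 1 under library totals. The list's median was 0.54 (camera adjusted p = 0.00163; adjusted p = 0.358 with an estimated correlation). C-8 sterol isomerase erg2 (TMEN_5219) rose from 25.1 ± 11.2 to 107 ± 31.9 CPM (2.09 ± 0.32; adjusted p = 0.00206), and delta(14)-sterol reductase (TMEN_4188) rose by 1.88 ± 0.28 (adjusted p = 0.00204). The last-step enzyme delta(24(24(1)))-sterol reductase (TMEN_3035) went the other way, at -1.14 ± 0.19 (adjusted p = 0.00285). The delta(7)-sterol 5(6)-desaturase (TMEN_2294) gave -0.82 ± 0.23 (adjusted p = 0.0225), with 0.0881 without control replicate 3 and 0.0603 without replicate 3 of 100 ug/ml.

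Cytochrome P450 genes, a family of monooxygenases, had 18 of 62 genes higher, 3 lower and 41 not past the test. The counts were 20 and 3 adjusted over the list alone, and 15 and 3 without replicate 2 of 100 ug/ml, or 24 and 0 by edgeR under library totals. The median was 0.61 (camera adjusted p = 0.00444; adjusted p = 0.583 with an estimated correlation, and 0.16 with members matched by Swiss-Prot name only), and 0.32 without replicate 2 of 100 ug/ml. The pyr3 monooxygenase (TMEN_9583) rose from 6.12 ± 0.39 to 71.4 ± 57.5 CPM (3.54 ± 0.50; adjusted p = 0.00188), or by 2.66 without replicate 1 of 100 ug/ml. Trichodiene oxygenase (TMEN_7584), on the contig of TMEN_7583, rose by 2.91 ± 0.42 (adjusted p = 0.00188). The yanC monooxygenase (TMEN_9504) gave -1.07 ± 0.30 (adjusted p = 0.0225), with 0.063, 0.0917 and 0.0584 without control replicate 1, control replicate 3 or replicate 1 of 100 ug/ml, and 0.0552 with only the 2 groups compared. A sterigmatocystin biosynthesis P450 (TMEN_8659) gave -0.90 ± 0.26 (adjusted p = 0.0237), with 0.0819, 0.103 and 0.0579 without control replicate 1, control replicate 3 or replicate 3 of 100 ug/ml.

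Sulfur and cysteine metabolism had 25 of 67 genes higher, 11 lower and 31 not past the test, 29 and 14 adjusted over the list alone, and 21 and 7 without replicate 2 of 100 ug/ml, or 33 and 5 under library totals. The median was 0.42 (camera adjusted p = 0.0309; adjusted p = 0.358 with an estimated correlation, and 0.0512 under library totals). Beside TMEN_2385, a 7,8-diamino-pelargonic acid aminotransferase of biotin synthesis (TMEN_6447) rose by 1.91 ± 0.29 (adjusted p = 0.00212). Sulfite oxidase (TMEN_8953), which turns sulfite into sulfate, fell from 429 ± 114 to 145 ± 42.3 CPM (-1.57 ± 0.32; adjusted p = 0.00546). An FAD synthase (TMEN_5494) gave -1.44 ± 0.35 (adjusted p = 0.0126), with 0.0603 without control replicate 3.

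Genes of ribosome biogenesis stood lower as a list. Of 96 genes, 43 fell, 2 rose and 51 did not pass, 50 and 2 when adjusted over the list alone, with a median of -0.57 (camera adjusted p = 2.48e-08; adjusted p = 0.583 with an estimated correlation). Without replicate 2 of 100 ug/ml 20 fell and 0 rose by edgeR, under upper-quartile factors 27 fell and 3 rose, and under library totals 15 fell and 3 rose. NSA2 (TMEN_4424), a factor of large ribosomal subunit assembly, fell from 104 ± 13.1 to 56.1 ± 1.49 CPM (-0.90 ± 0.18; adjusted p = 0.00526), and tsr1 (TMEN_9632) gave -0.93 ± 0.20 (adjusted p = 0.00658). The risers were an RNA helicase C550.03c (TMEN_9381, 0.82 ± 0.25; adjusted p = 0.0278) and ribosome assembly protein 1 (TMEN_7303, 0.70 ± 0.22; adjusted p = 0.0331). Without control replicate 1, control replicate 3, replicate 2 or replicate 3 of 100 ug/ml their adjusted p was 0.0895, 0.104, 0.0501 and 0.0848 for the helicase and 0.101, 0.121, 0.0944 and 0.0576 for TMEN_7303. Without replicate 2 of 10 ug/ml TMEN_7303 gave 0.0531, and with only the 2 groups compared the helicase gave 0.051 and TMEN_7303 0.0739.

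Transcription factor genes fell more often than they rose, with 66 of 240 lower, 29 higher and 145 not past the test. The counts were 80 and 34 adjusted over the list alone, and 62 and 18 without replicate 2 of 100 ug/ml. The median was -0.32 (camera adjusted p = 0.00444; adjusted p = 0.358 with an estimated correlation). Under library totals 39 were lower and 38 higher. Beside TMEN_5603, a fungal specific transcription factor gene (TMEN_5137) fell from 224 ± 49.7 to 36.3 ± 3.77 CPM (-2.63 ± 0.25; adjusted p = 0.000428) and a homeobox gene (TMEN_3820) gave -2.60 ± 0.34 (adjusted p = 0.00124). A sterol regulatory element-binding protein homolog (TMEN_9657), of a family that activates sterol synthesis genes, rose by 1.62 ± 0.32 (adjusted p = 0.00516).

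Mitochondrial ribosomal proteins passed the list test with a median of -0.26, or -0.14 without replicate 2 of 100 ug/ml (camera adjusted p = 0.0424; adjusted p = 0.919 with an estimated correlation), though 2 of 42 genes fell, 0 rose and 40 did not pass by edgeR. Adjusted over the list alone 1 fell, without replicate 2 of 100 ug/ml 1 fell, and under library totals 2 fell and 1 rose. A large subunit gene (TMEN_9041) gave -1.27 ± 0.27 (adjusted p = 0.0066), and the small subunit gene S9 (TMEN_5961) gave -0.84 ± 0.23 (adjusted p = 0.019). The list's adjusted p was 0.142 without control replicate 3, 0.375 without replicate 2 and 0.0905 without replicate 3 of 100 ug/ml, 0.105 under library totals, 0.168 with Swiss-Prot names only and 0.391 with fry. For TMEN_5961 it was 0.0514, 0.0719, 0.0507 and 0.0518 without control replicate 1, control replicate 3, replicate 2 or replicate 3 of 100 ug/ml.

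**Figure D3:**
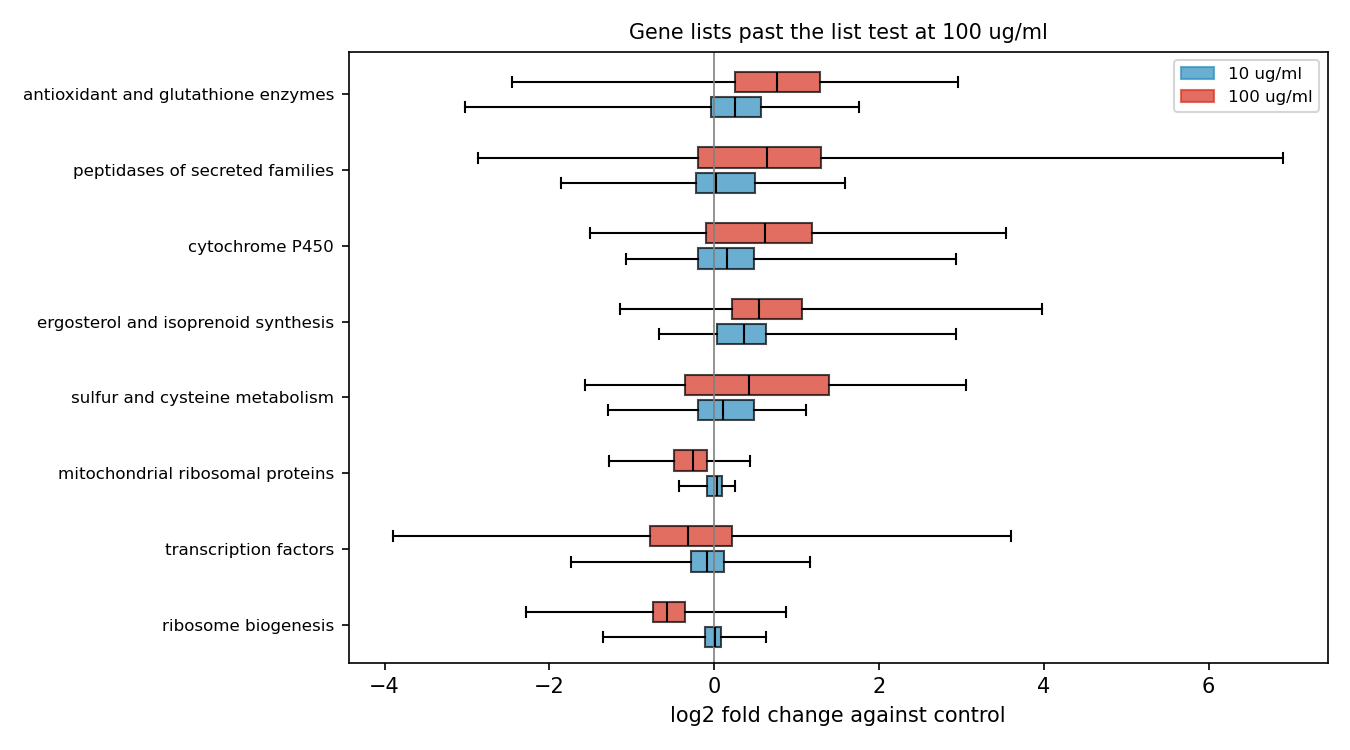
Log2 fold changes of the genes in the 8 lists past the test at 100 ug/ml, for 10 and 100 ug/ml against control; boxes show the quartiles and median, whiskers the lowest and highest gene. At 100 ug/ml medians ran from -0.57 for ribosome biogenesis to 0.76 for antioxidant and glutathione enzymes.

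The other 22 lists did not pass camera at 100 ug/ml, and the list p-values given below are those of camera. By fry, cell wall synthesis passed as lower (adjusted p = 0.0143) and chitinases and glycoside hydrolases as higher (adjusted p = 0.035). Counts of higher and lower genes are given over all genes tested, then adjusted over the list alone, then over all genes without replicate 2 of 100 ug/ml. The markers of other cell forms, conidia and development, gave 5 and 10 of 39 genes, 6 and 12, and 3 and 8 (median -0.15; adjusted p = 0.328), or 7 and 4 with a median of 0.10 under library totals. In that list a velvet-family regulator (TMEN_8592) fell from 1513 ± 711 to 306 ± 115 CPM (-2.31 ± 0.39; adjusted p = 0.00295), trehalose-phosphate synthase (TMEN_8769) gave -1.99 ± 0.33 (adjusted p = 0.00282), and the LAE1 homologs TMEN_3416 and TMEN_3953 gave 1.47 ± 0.27 and -1.71 ± 0.30 (adjusted p = 0.00439 and 0.00344). Cell wall synthesis gave 13 and 21 of 79, 15 and 21, and 8 and 20 (adjusted p = 0.559), with a median of 0.03 (0.00 without replicate 2 of 100 ug/ml) and a mean of -0.10, or 16 and 16 under library totals. The glucan synthase FKS1 (TMEN_8813), which makes the main glucan of the wall, fell from 2019 ± 84.3 to 687 ± 155 CPM (-1.56 ± 0.27; adjusted p = 0.00333), and an alpha-1,6-mannosyltransferase (TMEN_3454) gave -2.85 ± 0.27 (adjusted p = 0.000428). Chitinases and glycoside hydrolases gave 28 and 12 of 112, 29 and 13, and 27 and 15 (adjusted p = 0.198), or 35 and 11 under library totals, with endochitinase 1 (TMEN_9053) up by 2.14 ± 0.33 (adjusted p = 0.00215).

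Amino acid, peptide and ammonium transporters gave 9 and 20 of 63 genes, 10 and 24, and 5 and 19 (adjusted p = 0.0953), or 16 and 16 under library totals. The vacuolar transporter YPQ3 homolog (TMEN_4161) fell from 473 ± 95.7 to 70.9 ± 3.25 CPM (-2.74 ± 0.24; adjusted p = 0.000428). Major facilitator and sugar transporters gave 23 and 23 of 135, 23 and 24, and 18 and 22 (adjusted p = 0.887), or 31 and 17 under library totals, and ABC transporters 10 and 6 of 45, 10 and 7, and 6 and 5 (adjusted p = 0.823), with a median of -0.04 (-0.09 without replicate 2 of 100 ug/ml) and a mean of 0.16, or 11 and 6 with a median of 0.22 under library totals. Iron and copper uptake gave 10 and 10 of 53, 12 and 10, and 8 and 6 (adjusted p = 0.701), or 15 and 7 under library totals, with the siderophore transporter mirB (TMEN_2621) up by 3.41 ± 0.65 (adjusted p = 0.00559). Polyketide and peptide synthesis gave 13 and 5 of 57, 14 and 5, and 10 and 6 (adjusted p = 0.103), or 19 and 4 under library totals. Protein kinases and phosphatases gave 25 and 34 of 203, 25 and 34, and 20 and 32 (adjusted p = 0.198; median -0.14), or 33 and 25 with a median of 0.10 under library totals, with the kinase wis1 (TMEN_2225), which acts in a stress pathway, falling from 635 ± 160 to 98.8 ± 13.2 CPM (-2.69 ± 0.27; adjusted p = 0.000428).

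In carbon and energy metabolism, the TCA and glyoxylate cycles gave 11 and 1 of 38 genes, 11 and 1, and 10 and 1 (adjusted p = 0.088), or 12 and 1 under library totals. Aconitate hydratase (TMEN_8767) was the gene that fell (-1.58 ± 0.39; adjusted p = 0.0122), from 2869 ± 991 to 959 ± 388 CPM. Oxidative phosphorylation gave 6 and 1 of 89, 2 and 0 by edgeR, and 9 and 0 (adjusted p = 0.0953), or 20 and 1 under library totals. Glycolysis and gluconeogenesis gave 11 and 3 of 37, 13 and 4, and 9 and 4 (adjusted p = 0.324), or 14 and 3 under library totals. Fatty acid oxidation and peroxisome genes gave 22 and 14 of 116, 22 and 14, and 17 and 10 (adjusted p = 0.639), or 30 and 9 under library totals. Fatty acid and phospholipid synthesis gave 20 and 15 of 82, 23 and 16, and 17 and 6 (adjusted p = 0.601), or 24 and 8 under library totals, with delta(12) fatty acid desaturase (TMEN_7477) falling from 1327 ± 418 to 281 ± 104 CPM (-2.24 ± 0.37; adjusted p = 0.00276).

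In protein synthesis and turnover, cytosolic ribosomal proteins gave 2 and 2 of 98 genes, 0 and 1 by edgeR, and 1 and 3 (adjusted p = 0.194), with a median of -0.13 that turned to 0.11 without replicate 2 of 100 ug/ml, or 5 and 2 with a median of 0.08 under library totals. The genes that passed included the hydrolase C26A3.11 (TMEN_8558) and the splicing factor slu7 (TMEN_9206), which are not ribosomal proteins and were picked out after their values were seen. Translation factors and aminoacyl-tRNA synthetases gave 21 and 9 of 81, 21 and 10, and 15 and 6 (adjusted p = 0.601), or 23 and 5 under library totals. Heat shock proteins and chaperones gave 16 and 14 of 98, 16 and 13, and 13 and 14 (adjusted p = 0.648), or 20 and 12 under upper-quartile factors and 24 and 11 under library totals. Proteasome and ubiquitin genes gave 31 and 42 of 243, 31 and 41, and 31 and 34 (adjusted p = 0.701). These counts turned to 37 and 34 under upper-quartile factors and 47 and 24 under library totals. The median of the proteasome list was 0.06 and its mean -0.04, and the heat shock median was -0.03, or -0.09 without replicate 2 of 100 ug/ml and 0.20 under library totals. Autophagy and vacuole genes gave 10 and 17 of 119, 7 and 16, and 6 and 17 (adjusted p = 0.701; median 0.05, mean -0.06), or 17 and 12 under library totals, and protein secretion and ER folding 23 and 14 of 182, 20 and 11, and 23 and 13 (adjusted p = 0.198), or 30 and 10 under upper-quartile factors and 36 and 8 under library totals. DNA replication, repair and histones gave 21 and 9 of 136, 17 and 5, and 17 and 5 (adjusted p = 0.194), or 28 and 5 under library totals, with proliferating cell nuclear antigen (TMEN_1929) up by 1.5 ± 0.28 (adjusted p = 0.00442). Cytoskeleton and cell cycle genes gave 17 and 29 of 185, 13 and 26, and 16 and 24 (adjusted p = 0.882; median 0.11, mean -0.01), or 23 and 22 under upper-quartile factors and 31 and 15 under library totals.

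At 10 ug/ml, 2 genes changed against control, and both fell. Chanoclavine-I dehydrogenase (TMEN_6522, BFBS01016319.1, 14516 to 15672), an enzyme of ergot alkaloid synthesis, fell from 4.79 ± 0.94 to 0.12 ± 0.06 CPM (mean ± SD, n = 3), or from 237 to 6 counts, a log2 fold change of -5.22 ± 0.56 (SE; edgeR adjusted p = 0.00932). The multidrug resistance protein fnx1 gene (TMEN_7567, BFBS01016441.1, 9586 to 11767), a membrane transporter, fell from 55.9 ± 9.38 to 16.2 ± 3.48 CPM (-1.79 ± 0.23; adjusted p = 0.031), and lay at 15.7 ± 1.47 CPM at 100 ug/ml (-1.83 ± 0.23; adjusted p = 0.00115). At an unadjusted p under 0.05 there were 829 genes, where 396 are expected by chance, and the groups did not overlap for 1313 genes (16.6%, where chance gives 10%). DESeq2 called 118 genes, 49 higher and 69 lower, and limma-voom 3. The authors' deposited table held 281 genes past the threshold, 126 higher and 155 lower, including both genes called here.

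The adjusted p of TMEN_6522 was 0.0639 without control replicate 1, and 0.0945 and 0.15 without replicate 2 or 3 of 10 ug/ml. For TMEN_7567 it was 0.129 and 0.0825 without control replicate 1 or 3, 0.199 and 0.283 without replicate 2 or 3 of 10 ug/ml, and 0.0555 under the stricter count filter. That filter left TMEN_6522 untested. The number of genes called was 0 by edgeR without control replicate 1 or without replicate 2 or 3 of 10 ug/ml, 1 without control replicate 3, 4 without replicate 1 of 10 ug/ml, and 104 without control replicate 2, the library that lay among the 10 ug/ml libraries on the first principal component.

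The genes beside TMEN_6522 on its contig, chosen after their values were seen, include 4 more named for ergot alkaloid synthesis between positions 7966 and 17935. At 100 ug/ml tryptophan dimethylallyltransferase (TMEN_6519), the first enzyme of that pathway, fell from 23.8 to 5.48 CPM (-2.11 ± 0.35; adjusted p = 0.00285), and easE (TMEN_6520) gave -1.72 ± 0.41 (adjusted p = 0.0107). At 10 ug/ml TMEN_6519, TMEN_6520, easF (TMEN_6521) and easC (TMEN_6523) gave -1.62, -1.09, -2.85 and -3.02, with adjusted p = 0.202, 0.374, 0.202 and 0.154, so that none of these 4 passed. The fall at 100 ug/ml was not confined to these genes. Next to them a lumazine-binding domain gene (TMEN_6524) fell too (-3.36 ± 0.52; adjusted p = 0.00272), as did TMEN_6517 (-1.28 ± 0.27; adjusted p = 0.00638), while TMEN_6518 (-0.64 ± 0.41; adjusted p = 0.246) and TMEN_6525 (-1.04 ± 0.64; adjusted p = 0.232), between or beside them, did not pass.

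**Figure D4:**
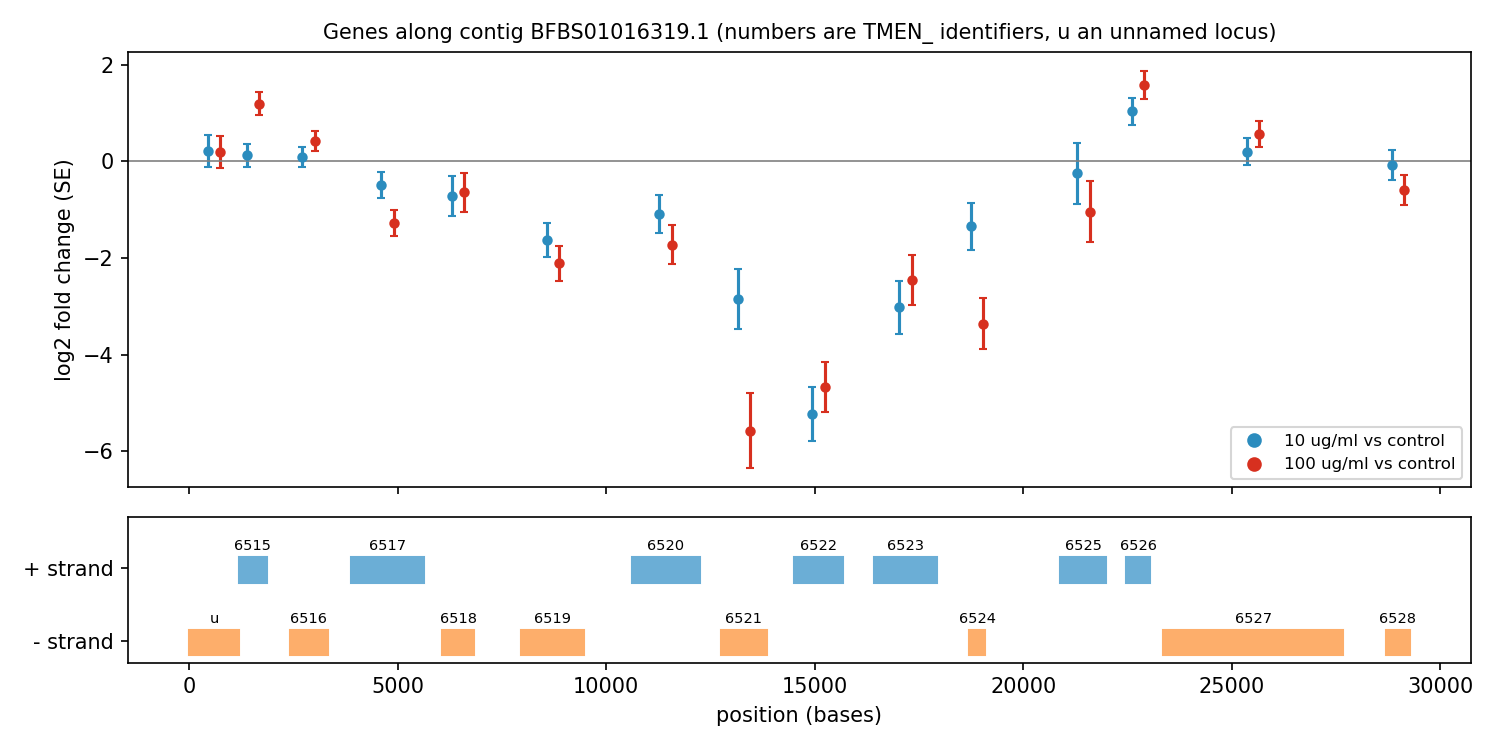
Genes along contig BFBS01016319.1 (horizontal, position in bases) with their log2 fold changes against control at 10 and 100 ug/ml (vertical); bars are SE. At 100 ug/ml the 6 genes from TMEN_6519 to TMEN_6524 lie at -5.57 to -1.72.

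As lists, ergosterol and isoprenoid synthesis and antioxidant enzymes stood higher at 10 ug/ml too. Both doses were compared with the same control libraries, so this is not independent of the result at 100 ug/ml. Of 10 splits of the control and 10 ug/ml libraries, 9 (the real one among them) gave at least the real 4 lists. In the ergosterol list 0 of 48 genes passed by edgeR, 5 were higher and 1 lower when adjusted over the list alone, 38 of 48 log2 fold changes were positive and the median was 0.36 (camera adjusted p = 7.17e-05; adjusted p = 0.575 with an estimated correlation and 0.128 with fry). Eburicol 14-alpha-demethylase (TMEN_8359), the target of azole antifungals, had 1.70 ± 1.47 CPM in control and 13.1 ± 2.45 CPM at 10 ug/ml (2.94 ± 0.58; adjusted p = 0.163), and erg2 (TMEN_5219) had 25.1 ± 11.2 and 77.1 ± 5.74 CPM (1.62 ± 0.31; adjusted p = 0.163). In the antioxidant list 0 of 84 genes passed by edgeR, 1 was higher and 1 lower when adjusted over the list alone, 58 fold changes were positive and the median was 0.25 (camera adjusted p = 0.000125; adjusted p = 0.705 with an estimated correlation and 0.168 with fry). The glutathione S-transferase TMEN_9343 had 18.1 ± 7.30 and 55.9 ± 6.55 CPM (1.63 ± 0.31; adjusted p = 0.163). Over all genes tested, 0 genes of either list passed by edgeR without replicate 2 of 100 ug/ml too.

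Oxidative phosphorylation stood higher at 10 ug/ml with a median of 0.13 and 70 of 89 fold changes positive, 0 of 89 genes past the test by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.0144; adjusted p = 0.901 with an estimated correlation and 0.791 with fry). NADPH dehydrogenase afvA (TMEN_4591) gave 1.07 ± 0.30 (adjusted p = 0.301) and alternative oxidase (TMEN_4107) 0.91 ± 0.40 (adjusted p = 0.464). The afvA gene entered by words in its description and may do other work. The p of the oxidative phosphorylation list was 0.0706 and 0.0835 without control replicate 1 or 3, and 0.474 without replicate 1 of 10 ug/ml. Amino acid, peptide and ammonium transporters stood lower, with a median of -0.21 and 23 of 63 fold changes positive (camera adjusted p = 0.0304; adjusted p = 0.901 with an estimated correlation and 0.504 with fry), 0 genes past the test by edgeR and 1 lower adjusted over the list alone, among them TMEN_4161 (-1.14 ± 0.23; adjusted p = 0.163). Their list p was 0.0835 without control replicate 3, 0.127 and 0.0576 without replicate 1 or 2 of 10 ug/ml, and 0.0711 with Swiss-Prot names only. The remaining 26 lists gave camera adjusted p = 0.0843 to 0.989, and the gene TMEN_7567 was the one called member in them, in the lists of major facilitator and of ABC transporters. It matched the ABC list by the words multidrug resistance protein, which do not make it an ABC transporter.

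Between the doses, single transcripts of secreted proteases again had the largest rises among the described genes named by the rule. Against 10 ug/ml the neutral protease TMEN_8004 rose by 5.77 ± 0.79, TMEN_6501 by 5.58 ± 0.97 and TMEN_4279 by 5.40 ± 0.63 on the log2 scale (adjusted p = 0.0115, 0.0221 and 0.00529). An antigenic thaumatin-like protein (TMEN_6037, BFBS01016247.1, 6063 to 6650) rose from 22.2 ± 18.3 to 354 ± 220 CPM (3.99 ± 0.77; adjusted p = 0.0249), with 74.9 ± 50.5 CPM in control, and TMEN_5620 rose by 3.57 ± 0.63 (adjusted p = 0.0216). Among the falls were the terpene synthase TMEN_5830 (-4.46 ± 0.40; adjusted p = 0.00195), the LysM gene TMEN_8673 (-3.42 ± 0.34; adjusted p = 0.00246) and the FAD-linked oxidoreductase afoF (TMEN_6688), from 2210 to 219 CPM (-3.33 ± 0.67; adjusted p = 0.0248). The peptide transporter ptr2 (TMEN_5475) gave -2.89 ± 0.69 and the efflux pump roqT (TMEN_6686) -2.84 ± 0.71 (adjusted p = 0.0355 and 0.0392). Of genes without a description, TMEN_8761 rose most (6.80 ± 1.26; adjusted p = 0.0235), from 12 to 1876 counts, and TMEN_4201 fell most (-5.44 ± 0.69; adjusted p = 0.00779).

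In all, 638 of 7920 genes (8.06%) differed between the doses by edgeR, 267 higher and 371 lower at 100 ug/ml, and 231 and 260 by 2-fold or more. The groups did not overlap for 2816 genes (35.6%, where chance gives 10%). Higher and lower calls were 354 and 231 under upper-quartile factors and 304 and 176 under library totals, which moved the median of all genes from 0.06 to 0.17 and 0.24. The authors' deposited table held 1270 genes, 578 higher and 692 lower, and 636 of them passed here with the same sign. The count was 33, 15 and 185 without replicate 1, 2 or 3 of 10 ug/ml, 330 without replicate 2 of 100 ug/ml and 305 without control replicate 1.

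The calls of TMEN_4279, TMEN_5830, TMEN_8673 and TMEN_4201 held without any one library. Without replicate 1 or 2 of 10 ug/ml the adjusted p was 0.0554 and 0.0763 for TMEN_8004, 0.0824 and 0.0889 for TMEN_6501, 0.0848 and 0.09 for TMEN_5620, 0.0857 and 0.0828 for TMEN_6688, 0.111 and 0.113 for TMEN_5475, 0.115 and 0.106 for TMEN_6686, and 0.0969 and 0.0904 for TMEN_8761. Without replicate 3 of 10 ug/ml it was 0.0579 for TMEN_5620, 0.0563 for TMEN_6688, 0.0668 for TMEN_5475, 0.079 for TMEN_6686 and 0.0617 for TMEN_8761. For TMEN_6037 it was 0.102 and 0.0585 without replicate 2 or 3 of 10 ug/ml. It was 0.0597 for TMEN_5475 without replicate 3 of 100 ug/ml, and 0.0573 and 0.0588 for TMEN_6686 without control replicate 1 or replicate 1 of 100 ug/ml. The replicate block and the fit of the 2 groups alone ended the calls of TMEN_5475 (0.053 and 0.0591) and TMEN_6686 (0.0629 and 0.0678), and limma-voom that of TMEN_8761 (0.0691). The log2 fold changes also moved. Without replicate 1 of 100 ug/ml they were 3.37 for TMEN_6037, 2.49 for TMEN_5620 and -6.13 for TMEN_4201. With limma-voom TMEN_5475 gave -3.68. Without replicate 2 of 100 ug/ml they were 4.84 for TMEN_6501, 4.58 for TMEN_4279 and -4.12 for TMEN_6688. Without replicate 3 of 100 ug/ml they were 4.83 for TMEN_8004 and 5.39 for TMEN_8761 (5.66 with limma-voom). Without replicate 1 of 10 ug/ml TMEN_6037 gave 4.92, and without replicate 3 of 10 ug/ml TMEN_6501 gave 6.27.

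Between the doses 7 lists passed, with the same 100 ug/ml libraries as against control, so these are not independent of the lists there. Peptidases of secreted families had 17 genes higher and 3 lower of 88, 27 and 4 adjusted over the list alone, and 16 and 0 by edgeR without replicate 2 of 100 ug/ml (median 0.44; camera adjusted p = 0.00079; adjusted p = 0.126 with an estimated correlation). Antioxidant and glutathione enzymes had 11 higher and 1 lower of 84, 19 and 1 adjusted over the list alone, and 7 and 0 without that library (median 0.43; camera adjusted p = 0.00023; adjusted p = 0.381 with an estimated correlation). Cytochrome P450 genes had 6 higher and 0 lower of 62 by edgeR, 7 and 0 adjusted over the list alone, and 3 and 0 without that library (median 0.40, or 0.19 without it; camera adjusted p = 0.000843; adjusted p = 0.458 with an estimated correlation and 0.0599 with fry). Sulfur and cysteine metabolism had 11 higher and 1 lower of 67, 13 and 4 adjusted over the list alone, and 7 and 0 without that library (median 0.25; camera adjusted p = 0.0296; adjusted p = 0.381 with an estimated correlation). Its adjusted p was 0.0521 without replicate 3 of 10 ug/ml, 0.0536 without replicate 2 of 100 ug/ml and 0.0527 under library totals.

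Examples were adenylyl-sulfate kinase (TMEN_3591) and sulfate permease 2 (TMEN_4499), which take up and activate sulfate, at 2.75 ± 0.53 and 2.55 ± 0.50 (adjusted p = 0.0235 and 0.0242), and the molybdenum cofactor sulfurase TMEN_5824 at 1.41 ± 0.22 (adjusted p = 0.0147). The glutathione S-transferase F10 gene (TMEN_2896) rose by 2.5 ± 0.44 and TMEN_2385 by 1.60 ± 0.29 (adjusted p = 0.0212 and 0.0211), the P450 genes TMEN_9583 and TMEN_7584 by 3.40 ± 0.50 and 2.10 ± 0.40 (adjusted p = 0.0115 and 0.0229). Without replicate 1 or 2 of 10 ug/ml the adjusted p was 0.0824 and 0.0828 for TMEN_2896, 0.0834 and 0.0835 for TMEN_2385, 0.0687 and 0.0763 for TMEN_9583, 0.0869 and 0.0935 for TMEN_7584, and 0.0694 and 0.0783 for TMEN_5824. Without replicate 1 of 100 ug/ml the log2 fold change of TMEN_9583 was 2.52.

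Ribosome biogenesis had 15 of 96 genes lower and 0 higher at 100 ug/ml than at 10 ug/ml by edgeR, 52 and 2 adjusted over the list alone, and 1 and 0 without replicate 2 of 100 ug/ml (2 and 0 under upper-quartile factors, 1 and 0 under library totals; median -0.59; camera adjusted p = 3e-12; adjusted p = 0.437 with an estimated correlation). NSA2 (TMEN_4424) gave -0.83 ± 0.18 (adjusted p = 0.0263), with 0.0871, 0.114 and 0.057 without replicate 1, 2 or 3 of 10 ug/ml. Transcription factors had 21 of 240 lower and 3 higher, 24 and 4 adjusted over the list alone, and 11 and 1 without replicate 2 of 100 ug/ml, with a median of -0.18, or 12 and 4 with a median of 0.01 under library totals (camera adjusted p = 0.00569; adjusted p = 0.381 with an estimated correlation). TMEN_5603 and TMEN_5137 fell again (-2.62 ± 0.36 and -1.72 ± 0.24; adjusted p = 0.00779 for both), and TMEN_5137 had adjusted p = 0.0551 without replicate 2 of 10 ug/ml. Mitochondrial ribosomal proteins had a median of -0.28, or -0.11 without replicate 2 of 100 ug/ml, with 0 of 42 genes past the test by edgeR, 0 adjusted over the list alone and 0 without replicate 2 of 100 ug/ml (camera adjusted p = 0.0129; adjusted p = 0.827 with an estimated correlation). That list gave adjusted p = 0.24 without replicate 1 of 10 ug/ml, 0.294 without replicate 2 of 100 ug/ml, 0.11 with Swiss-Prot names only and 0.467 with fry. The other 23 lists gave camera adjusted p = 0.0724 to 0.976, among them ergosterol and isoprenoid synthesis at 0.164. By fry, cell wall synthesis passed as lower and chitinases and glycoside hydrolases as higher (adjusted p = 0.0344 for both).

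Both genes called at 10 ug/ml, TMEN_6522 and TMEN_7567, were also called at 100 ug/ml, and lower in both. Both comparisons used the same control libraries, so part of any link between them is chance. In 50 simulations with effects at 100 ug/ml alone, 0.24 genes were called at 10 ug/ml and 0.08 at both doses on average (0 to 1). Independent lists would share 0.308 genes in the same direction. Across all genes the log2 fold changes of the doses correlated at 0.664. Simulations without an effect at either dose gave 0.5 (0.463 to 0.521), and those with effects at 100 ug/ml alone gave 0.201 (0.162 to 0.238). The covariance of the log2 fold changes was 0.306 against 0.0666 simulated without an effect, a difference of 0.239. A split with control replicates 1 and 3 and replicate 1 of 10 ug/ml as control gave a higher covariance, 0.329. The excess over the simulations is therefore not particular to the real groups. The control libraries are too few to split into 2 groups of 2, so part of the excess may come from the shared controls.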

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

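Library totals alone, Swiss-Prot names only and the list counts without replicate 2 of 100 ug/ml were chosen after the results were seen, and the other alternatives before.

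The count of 2 genes at 10 ug/ml against control was 118 with DESeq2 (49 higher, 69 lower), 0 by edgeR with the stricter filter (where 829 genes had an unadjusted p under 0.05 with the usual filter, and limma-voom called 3), 7 with only the 2 groups compared, 5 with the replicate block and 1 with library totals. Under the stricter filter TMEN_6522 was not tested, and TMEN_7567 was tested and did not pass. Leaving out 1 library gave 0 to 104 genes, with 104 without control replicate 2. The number of genes called at both doses was 110 with DESeq2, 0 by edgeR with the stricter filter, 6 with only the 2 groups compared, 5 with the block and 1 with library totals, and 0 to 104 with 1 library left out. The 2491 genes at 100 ug/ml against control were 1613 with a fold threshold of 2, which by its construction can only lower the count, and 1170 to 2643 with 1 library left out. The 638 genes between the doses were 1436 with DESeq2 and 15 to 751 with 1 library left out. The lowest count came without replicate 2 of 10 ug/ml. Fewer samples enter those fits, and beyond that the cause was not tested.

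With the correlation estimated per list, 0 lists passed camera at 10 ug/ml against control (4 at the preset value), at 100 ug/ml against control (8) and between the doses (7). Fry called 0, 9 and 7, of which 0, 7 and 5 were lists that camera called. The others were cell wall synthesis, and chitinases and glycoside hydrolases. Correlation between genes does not alone account for the lists lost with the estimate. For the peptidases at 100 ug/ml against control the estimate was 0.005, below the preset 0.01. Their camera adjusted p still went from 0.00444 to 0.279. Leaving out 1 library gave 3 to 8, 7 to 10 and 6 to 10 lists, and the 8 came without control replicate 2 and without replicate 3 of 10 ug/ml. The cause was not tested.

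The replicate number as a block gave 5, 2290 and 580 genes and 4, 8 and 7 lists. Samples of the same number correlated across genes at -0.224 to 0.316 after removal of the group means, and 3 of 9 samples correlated best with their own number, so the numbers were not read as pairs and the fit without the block was kept.

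Of 75 named results, 44 kept their call and 75 their sign in every alternative in which the gene was tested, though sizes moved. Among called genes, 2398 of 2491 at 100 ug/ml against control and 635 of 638 between the doses had no overlap between the groups. For such genes leaving out a library can hardly turn the sign, so the kept signs were largely set by the choice of genes. The stricter filter tested 70 of them. With 3 libraries per group, 28 to 38% of simulated 2-fold changes and 99 to 100% of 4-fold ones were recovered. Small changes are thus missed more often. The simulated changed genes had a mean of at least 50 counts and the spread typical of their level. Real genes with fewer counts or a wider spread can be missed at 4-fold too. At 10 ug/ml against control TMEN_2096 gave 3.46 on the log2 scale and did not pass (edgeR adjusted p = 0.2145).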

Other observations

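The search for runs of adjacent genes and the family test were chosen after the results were seen, as were the tests of depth, mislabelling and conidia in replicate 2 of 100 ug/ml and of chance gene order. At 100 ug/ml, 25 runs of at least 4 adjacent genes changed in one direction against control, where shuffled gene orders gave 6.93 on average and 16 at most in 1000 shuffles. Beside the phosphopantetheine gene TMEN_2619 rose a pair of siderophore iron transporters mirB (TMEN_2620, 1.96 ± 0.42; TMEN_2621, 3.41 ± 0.65) and a WSC domain gene (TMEN_2622, 3.60 ± 0.73; adjusted p = 0.00712). Fungal siderophores are peptides that bind iron, made by enzymes with phosphopantetheine carrier domains. A copalyl diphosphate synthase gene (TMEN_9865) rose by 2.69, next to a P450 monooxygenase (TMEN_9866, 1.90). Myo-inositol transporter genes TMEN_6639 and TMEN_6640 gave -2.11 ± 0.30 and -2.44 ± 0.34 beside a polyamine transporter (TMEN_6641, -1.70 ± 0.30; adjusted p = 0.00361).

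Of 133 Pfam families with a background of 2632 genes, 3 held more lower genes and 2 more higher genes at 100 ug/ml than independent draws give. Genes controlled together are not independent draws, so these p-values may be too small. The DEAD-box family shares genes with the ribosome biogenesis list, such as TMEN_9381, so those results are not separate. DEAD-box helicases, which unwind RNA, had 14 of 28 genes lower (4.5 expected; adjusted p = 0.00755), among them DBP2 (TMEN_8450, -1.41 ± 0.29) and DED1 (TMEN_6113, -1.45 ± 0.33), while DBP5 (TMEN_6560, 1.07 ± 0.21) and TMEN_9381 (0.82 ± 0.25) rose. KH domain genes had 6 of 7 lower (1.12 expected; adjusted p = 0.0134) and RRM domain genes 18 of 52 (8.36 expected; adjusted p = 0.0453). The C-terminal domain of glutathione S-transferases had 6 of 8 genes higher (1.5 expected; adjusted p = 0.0453), among them gliG (TMEN_6860, 2.94 ± 0.86). An alpha/beta hydrolase family had 9 of 16 higher (2.99 expected; adjusted p = 0.0453), among them proline iminopeptidase (TMEN_6401, 1.82 ± 0.27).

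In replicate 2 of 100 ug/ml the ammonium transporter MEP1 (TMEN_509) stood at 6550 CPM against 240 and 150 in replicates 1 and 3, and NADP-specific glutamate dehydrogenase (TMEN_3937) at 17500 against 891 and 964. Phosphoenolpyruvate carboxykinase (TMEN_7931) stood at 321 CPM against 4810 and 3120, and the median of cytosolic ribosomal protein genes lay 0.86 lower on the log2 scale. A low depth was argued against by 18045074 counts (lowest other 15904732), and a label taken from another group by a lowest correlation of 0.926 with its own group and a highest of 0.918 with any other, and by the genes called at 100 ug/ml without it. Of the 2072 of these that were also tested with all libraries, 84% lay nearer to the other 100 ug/ml libraries than to control, and 73.5% nearer to them than to 10 ug/ml. Conidia (median of the list -0.055, with 0.16 as the upper bound from 10000 random lists and 19 members higher and 20 lower) and a stronger response to the dose (correlations of 0.048 and 0.15) stay open.

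Log2 fold changes at 100 ug/ml correlated at 0.257 over 7448 pairs of adjacent genes, and the highest of 1000 shuffles gave 0.044, which argues against a chance order. Reads running from one gene into the next were argued against by divergent neighbours at least 1000 bases apart, which correlated at 0.387 (834 pairs) with 0.104 as the highest shuffle. A property of the libraries that does not depend on the dose stays open, since differences between control libraries gave up to 0.228. Shared control of neighbouring genes may also contribute, and these values cannot tell it from that property.

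Few genes passed at 10 ug/ml. Replicate 2 of 100 ug/ml raised the shared spread (coefficient of variation 0.291, or 0.254 without it), but 2 genes passed without that library. This argues against it as the sole reason for the few calls. A fit with fewer libraries also calls genes less easily, so a part played by that library is not excluded. A spread shared with the 100 ug/ml libraries may contribute, since a fit of the 2 groups alone gave 7 genes. Control replicate 2 may contribute too, since 104 genes passed without it. That library correlated more closely with each 10 ug/ml library than with the other control libraries. Whether its label is right was not tested. Of the genes called at 100 ug/ml, 91.7% had the same sign at 10 ug/ml, above the 66.3% that was the highest in 50 simulations with effects at 100 ug/ml alone. This was left open after the splits were seen, because another of 20 ordered splits of the control and 10 ug/ml libraries gave 92.8%, with control replicates 1 and 3 and replicate 1 of 10 ug/ml as control.

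The 3 against 3 samples of each comparison make 10 splits, too few for a share under 0.05. In every other split each side holds libraries of both groups, so genes that differ between the groups widen the spread. A count of 0 genes there is partly set by that, and it was not read as support for the real groups. For genes changed, 1 split (the real one) reached the real value in each comparison, with 2, 2491 and 638 genes and 0 by edgeR as the highest other; at an unadjusted p under 0.05 the real splits gave 829, 3519 and 2413 genes, and limma-voom called 3, 2485 and 680. For lists at 10 ug/ml against control, 9 splits reached the real 4 and the highest other gave 17. That split set control replicates 1 and 3 and replicate 3 of 10 ug/ml apart from the others, and why it gave as many was not tested. For 100 ug/ml against control 5 splits reached the real 8 (highest other 13), and between the doses 7 reached the real 7 (highest other 11).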
